A study of Mus musculus with 6 samples.

How the data were processed

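Total RNA from isolated mouse heart cells was hybridised to 6 one-colour Affymetrix arrays, 2 for each of 3 groups. The groups were cardiomyocytes and cardiac fibroblasts from hearts at postnatal day 1, and cardiomyocytes from hearts at 8 weeks of age, all from the C57BL/6J strain. Per the labels, the neonatal cells came from animals of both sexes and were separated on Percoll, a density medium. The adult cells came from males and were released by perfusing the heart through the aorta (the Langendorff method). Age, sex and isolation method therefore differ together between the adult and the neonatal groups. The labels also describe dissociation with trypsin and collagenase, and plating of cells with a check for remaining cardiomyocytes by a mitochondrial dye. They do not say whether the 2 arrays of a group came from separate litters or preparations, so the p-values measure the spread between these arrays, which may be technical.

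The deposited table holds log2 expression values per probe set. They are RMA values per the submitters' processing notes; RMA corrects background, normalizes by quantiles and summarises the probes of a probe set. Its version, and whether the 6 arrays were processed together, is not given in the sources used here. Array medians lay between 5.60 and 5.67, lower quartiles between 4.19 and 4.37, and maxima between 14.4 and 14.6. Upper quartiles were 7.45 and 7.58 on the adult arrays and between 7.68 and 7.78 on the others. RMA gives no detection call. Log2 differences can be compressed for genes near the floor or near the top of the range, which was not measured here. The number of arrays limits the precision.

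The table has 45101 probe sets, of which 64 are controls. GEO's platform annotation named 34945 probe sets to 1 gene, and 932 to several genes; 9160 were unnamed here. Symbols were checked against the RefSeq gene table, and 0 needed an update. Where a gene had several probe sets (9010 genes), the probe set with the highest mean over all 6 arrays was used, which gave 18193 genes. No coordinates are given, because the sources used here name no genome build.

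Groups followed the source name, which the cell type field also gives. The titles of the 2 neonatal replicate 1 arrays name the other cell type. The grouping was fixed before the data were examined, with the titles' grouping and the removal of both arrays as alternatives.

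All 6 arrays entered a linear model with 3 group means in limma 3.58.1 (R 4.3.3), with lmFit and eBayes. It left 3 residual degrees of freedom, to which the moderated variance added 2.18. The 3 comparisons were tested two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 18193 genes, with a threshold of 0.05. In the text, higher or lower gives a direction of means, and rose, fell or changed is kept for genes or lists past that threshold. On simulated data with 50 changed genes of each size, 46% of differences of 2 log2 units and 90% of those of 6 log2 units were recovered between neonatal cardiomyocytes and fibroblasts. For adult against neonatal cardiomyocytes the recovered shares were 48% and 96%, and for adult cardiomyocytes against fibroblasts 36% and 90%. At 4 log2 units the shares were 70%, 76% and 80% in the same order of comparisons. At 1 log2 unit they were 0%, 2% and 2%, so the absence of a call says little about differences of that size. The changed genes were chosen at random, with normal noise at each gene's own residual SD. The shares also depend on how many genes change, and the simulated number need not match the real comparisons. Sarcomere genes differed by −2.73 in the median between the fibroblast arrays (replicate 1 minus replicate 2), so these shares need not hold for them.

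Before the data were examined, 28 gene lists were fixed. They cover the sarcomere, calcium handling and ion channels, cardiac transcription factors, fetal and adult isoforms, collagens and matrix, fibroblast markers, TGF beta and myofibroblast genes, 5 lists of metabolism, cell cycle genes and inhibitors, imprinted genes and paracrine factors. The rest are markers of endothelial, smooth muscle, leukocyte, erythroid, epicardial, Schwann and fat cells, 3 lists of stress and inflammation, and sex-linked genes. Lists share members: Des, for example, is in the sarcomere and the smooth muscle list. Each was tested with camera against all other genes, with a preset inter-gene correlation of 0.01 and with an estimated one, adjusted over the 28 lists. With the estimated correlation, camera also uses only the 3 residual degrees of freedom, which raises p-values even where the correlation is small. Counts are also given adjusted over the list alone. Older symbols in a list were matched through synonyms; a current symbol with no probe set named to it alone, such as H19, Gpi1, Hcn4 or Loxl2, was left out as unmeasured.

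Genes named in the text followed a rule fixed at the same time. It takes, among genes past the threshold whose arrays did not overlap between the groups, the 8 largest differences in each direction (5 for adult cardiomyocytes against fibroblasts), leaving out uncharacterised transcripts. It adds up to 4 members of each list with the largest absolute difference, and the genes of the label check. Members of a list with 5 or fewer calls were also named. Those outside the rule, chosen after their values were seen, were Cacnb2, Hrc, Kcnq1, Loxl1, Ndufs7, Perm1, Ppara, Sgca, Tnnt1 and Xirp1 between the neonatal cell types, Col4a1, Fgf16, Junb, Mmp14 and Myh10 between the cardiomyocyte groups, and Bnip3, Cd163, Egln3, Herpud1 and Lyz1 between adult cardiomyocytes and fibroblasts.

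Alternatives were an intensity trend in eBayes, quantile normalization, median centring, leaving out the dimmest 40% of genes, the mean of a gene's probe sets, every probe set by itself, the replicate number as a block, only the 4 arrays compared, the titles' grouping, removal of both arrays with disagreeing labels, each array left out, and a 2-fold minimum. Removal of both neonatal replicate 2 arrays was added after their marker levels were seen, and the division of the fibroblast arrays between the comparisons after the counts were seen. Same-numbered arrays deviated together in every pair of groups, with correlations of 0.183, 0.268 and 0.207 across genes. GEO numbered the 3 arrays of each replicate number in succession. The 2 runs of numbers lie far apart, as they would if deposited separately. The labels do not say what a replicate number marks, and with 2 arrays per group each pair of groups gives 1 correlation. The pairing is therefore a hint from the data and the numbering. The replicate block is given beside each result whose call it changed, which was decided after both fits had been seen. Figures were drawn with matplotlib 3.10.9.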

Results

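Gene expression was measured in isolated heart muscle cells and cardiac fibroblasts, the connective tissue cells of the heart. The 6 arrays fall into 3 groups of 2: neonatal cardiomyocytes, neonatal cardiac fibroblasts and adult cardiomyocytes. The comparisons ask which transcripts mark each cell type in the newborn heart and which differ between newborn and adult cardiomyocytes. Values are log2 RMA values, given as mean ± SD over n = 2 arrays, and SE is the limma standard error of a difference. Across 18193 genes, the Pearson correlation between the arrays of a group was 0.957 for neonatal cardiomyocytes, 0.963 for fibroblasts and 0.974 for adult cardiomyocytes. Neonatal cardiomyocyte replicate 2 and fibroblast replicate 2, arrays of different groups, correlated at 0.958.

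The titles of the neonatal replicate 1 arrays disagree with their other labels, so marker genes were examined first. The cardiac myosin Myh6 lay at 14.39 ± 0.08 in neonatal and 14.48 ± 0.01 in adult cardiomyocytes, near the top of the range, and at 10.89 ± 2.01 in fibroblasts. Cardiac troponin I, Tnni3, measured 6.07 on fibroblast replicate 1 and 10.86 on fibroblast replicate 2, against 13.65 ± 0.09 in neonatal cardiomyocytes. The median of the 24 sarcomere genes was 13.24 and 12.84 on the neonatal cardiomyocyte arrays, 7.31 and 9.71 on the fibroblast arrays, and 13.55 and 13.48 on the adult arrays. The 40 collagen and matrix genes ran the other way, with medians of 9.32 and 9.78, 11.86 and 11.80, and 7.07 and 8.46 in the same order. The array grouped as cardiomyocyte replicate 1 thus had the higher sarcomere and the lower matrix median of its pair. Of the fibroblast arrays, replicate 2 had the higher sarcomere median, and its median of 23 leukocyte genes was 8.43 against 11.49.

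**Figure D1:**
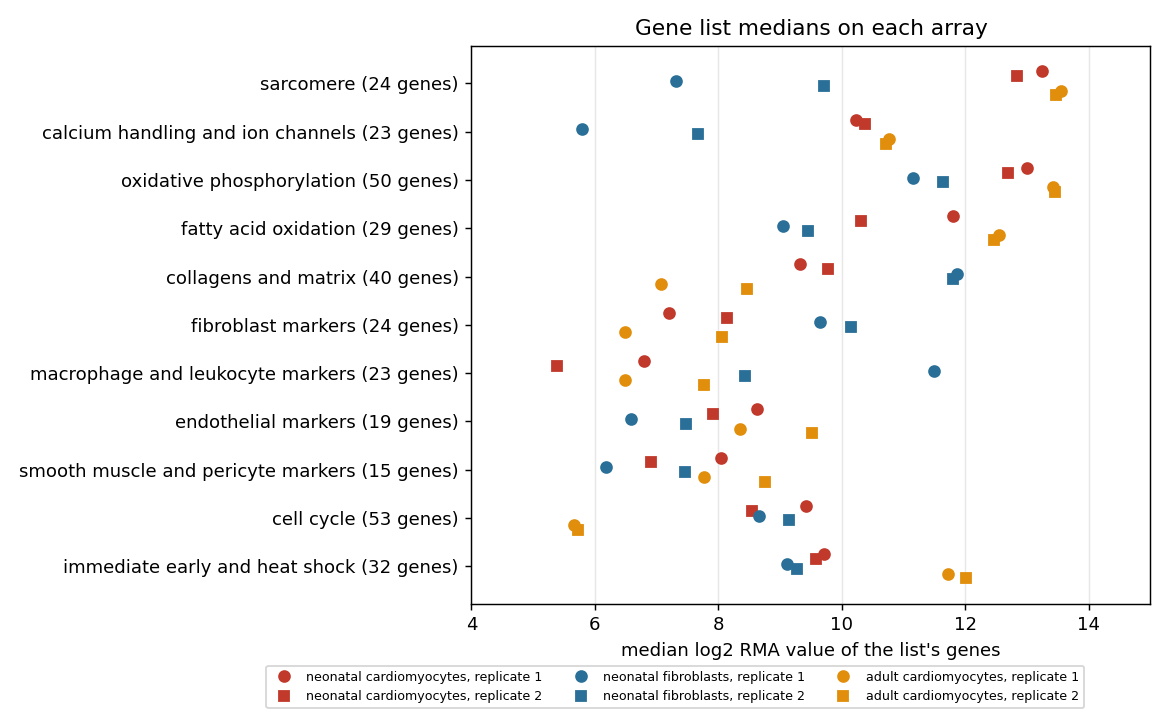
Median log2 RMA value (horizontal axis) of the genes of fixed lists (vertical axis, with the number measured) on each array; colour gives the group and shape the replicate. The sarcomere median is 7.31 and 9.71 on the fibroblast arrays and lies between 12.84 and 13.55 on the cardiomyocyte arrays, while the cell cycle median is 5.66 and 5.73 on the adult arrays and between 8.54 and 9.41 on the others.

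Neonatal cardiomyocytes differed from neonatal fibroblasts in 149 genes, 123 higher and 26 lower. With the replicate block limma called 0 genes and 3678 passed at unadjusted p under 0.05; the genes named here as called had adjusted p between 0.0537 and 0.0645 there, with the same differences. Among the genes named by the rule, the largest increases past the threshold were in Txlnb, a muscle-enriched taxilin, at 10.21 ± 0.09 against 4.55 ± 1.12 (50.4-fold, adjusted p = 0.0424), and in Klhl41, a sarcomere-associated kelch protein (34.3-fold). Kcnj3, a subunit of the acetylcholine-activated potassium channel, was 33.7-fold higher, and Rnf207 33.5-fold higher. Strip2, Tox3, the calcium-binding protein Casq1 and the muscle methyltransferase Smyd1 followed, at 29.7-, 28.3-, 27.0- and 26.9-fold. All 24 sarcomere genes had higher means in cardiomyocytes, with a median log2 difference of 4.29, but only Xirp1 (4.52) and the intermediate filament gene Des (3.25) rose when all genes were tested. Adjusted over the list alone, 23 rose. The LIM protein gene Csrp3 had a difference of 5.84 ± 0.97 (SE) with an adjusted p of 0.0713, and Tnni3 a difference of 5.18 with 0.188; the SD of the fibroblast arrays was 2.10 and 3.38.

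Of 23 calcium and channel genes, 4 rose (Kcnj3 by 5.07, Cacnb2 by 4.27, Hrc by 3.16 and Kcnq1 by 2.84) and 16 adjusted over the list alone, with a median of 3.16. Among 23 cardiac transcription factor genes Smyd1 alone rose, and 10 adjusted over the list alone (median 1.15). The sarcoglycan Sgca rose by 2.28 in the adult isoform list of 22 (17 adjusted over the list alone, median 3.94), and the slow troponin Tnnt1 by 3.89 in the fetal isoform list of 19 (9 adjusted over the list alone, median 2.65). Energy metabolism ran in the same direction. All 50 oxidative phosphorylation genes and all 29 fatty acid oxidation genes had higher means in cardiomyocytes, with medians of 1.35 and 1.60. Only Ndufs7 of the first list (1.67) and 0 of the second rose among all genes, against 50 and 19 adjusted over the list alone; limma passed 23 of the second at unadjusted p under 0.05. Pdk4, which restrains glucose oxidation, had a difference of 4.54 (adjusted p = 0.0605) and Cox7a1 4.71 (0.108). In the TCA cycle list of 23, Mdh1 rose by 2.20 (4 of its 5 probe sets had that sign), and 21 genes adjusted over the list alone (median 1.68). In the glycolysis list of 21, Ldhb rose by 3.11, and 13 adjusted over the list alone (median 1.09). The regulators Esrrg (4.30), Ppargc1b (3.83), Perm1 (3.51) and Ppara (2.63) rose among 20 metabolic regulators, with 9 adjusted over the list alone and a median of 0.68. In camera these lists were higher in cardiomyocytes, with adjusted p between 1.14e-34 and 2.27e-05. The calls were lost with an estimated correlation, where adjusted p = 0.346 for fatty acid oxidation and 0.294 for each of the others.

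Lower in cardiomyocytes than on the fibroblast arrays were Scel, which encodes sciellin (63.1-fold), and the matricellular gene Ccn5 (48.8-fold). The other Scel probe set pointed the other way. Ms4a7, a macrophage gene, was 44.9-fold lower in cardiomyocytes, and Kcne4, a potassium channel subunit, 25.9-fold. Tcf21, a transcription factor of cardiac fibroblasts and their precursors, measured 7.61 ± 0.33 in cardiomyocytes and 12.20 ± 0.15 in fibroblasts (24.2-fold, adjusted p = 0.0424). Kcnj15, Lgi2 and the myeloid lectin Clec4d were 19.7-, 13.9- and 13.2-fold lower in cardiomyocytes; 2 of the 3 Kcnj15 probe sets had that sign. Of 40 collagen and matrix genes, 36 had lower means in cardiomyocytes and the median was −1.98, but only the crosslinking enzyme gene Loxl1 fell (−3.18), and 5 adjusted over the list alone. Col8a1 differed by −4.99 ± 2.05 (SE), adjusted p = 0.323. Tcf21 alone of 24 fibroblast markers (median −1.23) and Itgb5 alone of 22 TGF beta and myofibroblast genes (−1.91, median −0.95) fell, with 3 and 1 adjusted over the list alone. The 23 leukocyte markers had a median of −3.73, with 0 that fell in limma among all genes, 17 at unadjusted p under 0.05 and 13 adjusted over the list alone; C1qa differed by −5.22 (adjusted p = 0.0998) and Cd68 by −4.24 (0.0832). On the fibroblast arrays the leukocyte median was 11.49 and 8.43, and which cells of the preparations these transcripts came from was not tested. Ifit3, an interferon-induced gene, fell by 2.68 among 29 inflammation genes (median −0.96), alone on both adjustments. In camera these lists were lower in cardiomyocytes, with adjusted p between 1.22e-11 and 0.000389. With an estimated correlation the calls were lost: adjusted p = 0.294 for matrix, 0.357 for fibroblast markers, 0.435 for TGF beta genes, and 0.387 for leukocytes and for inflammation.

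Markers of other cells also differed. Endothelial markers (19 genes) had a median of 1.43 towards cardiomyocytes, with 0 called in limma among all genes, 7 at unadjusted p under 0.05 and 2 adjusted over the list alone; the camera adjusted p was 0.000502, and adjusted p = 0.387 with an estimated correlation. Epicardial markers (14 genes) had a median of −1.27, with 0 called, 4 at unadjusted p under 0.05 and 2 adjusted over the list alone; the camera adjusted p was 0.00411, and adjusted p = 0.393 with an estimated correlation. Without neonatal cardiomyocyte replicate 1 or fibroblast replicate 1 the epicardial call ended, with adjusted p of 0.0518 and 0.232. The 32 immediate early and heat shock genes had a median of 0.32, with 0 called, 9 at unadjusted p under 0.05 and 4 adjusted over the list alone; the camera adjusted p was 0.000312, and adjusted p = 0.346 with an estimated correlation. The 53 cell cycle genes were not called between the neonatal cell types, with a median of 0.01, 0 called on either adjustment and 2 in limma at unadjusted p under 0.05; camera pointed down (adjusted p = 0.375). Camera also made no call for the other 9 lists, with adjusted p between 0.0531 and 0.922. Their medians were 0.13 for cell cycle inhibitors, 0.26 for imprinted genes, −0.29 for paracrine factors, 1.06 for smooth muscle and pericyte markers, 0.01 for erythroid markers (camera direction down), −0.08 for Schwann and neural markers, 0.13 for fat cell markers, −0.48 for hypoxia and amino acid stress genes and −0.02 for sex-linked genes. Among these Fgf1, a growth factor gene, rose by 3.13 in the paracrine list, and Des is also a member of the smooth muscle list; adjusted over the list alone 4 rose and 1 fell in the first, 2 rose and 1 fell in the second, and 1 Schwann and neural marker fell.

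The smallest adjusted p between the neonatal cell types was 0.0424, and 45.4% of genes had non-overlapping arrays, against 33.3% by chance. The count fell to 0 without neonatal cardiomyocyte replicate 1, fibroblast replicate 1, or either adult array (limma passed 1909, 1964, 2532 and 2532 genes at unadjusted p under 0.05). It was 437 without neonatal cardiomyocyte replicate 2 and 423 without fibroblast replicate 2, and 0 with the groups that the titles give, where 232 passed at unadjusted p under 0.05. Leaving out either adult array gives the same fit here, since adult cells do not enter this difference and a lone adult array adds no residual. List counts moved with the number of genes called, for more lists than those given here. Without fibroblast replicate 2, 21 sarcomere, 13 calcium and channel, 12 adult isoform, 8 oxidative phosphorylation, 7 regulator, 5 transcription factor, 5 fetal isoform and 4 glycolysis genes rose. Without neonatal cardiomyocyte replicate 2, 1 sarcomere and 7 TCA cycle genes rose and 5 matrix genes fell. Without any of the other 4 arrays 0 members of these lists were called, while limma passed 19 to 23 sarcomere genes at unadjusted p under 0.05.

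**Figure D2:**
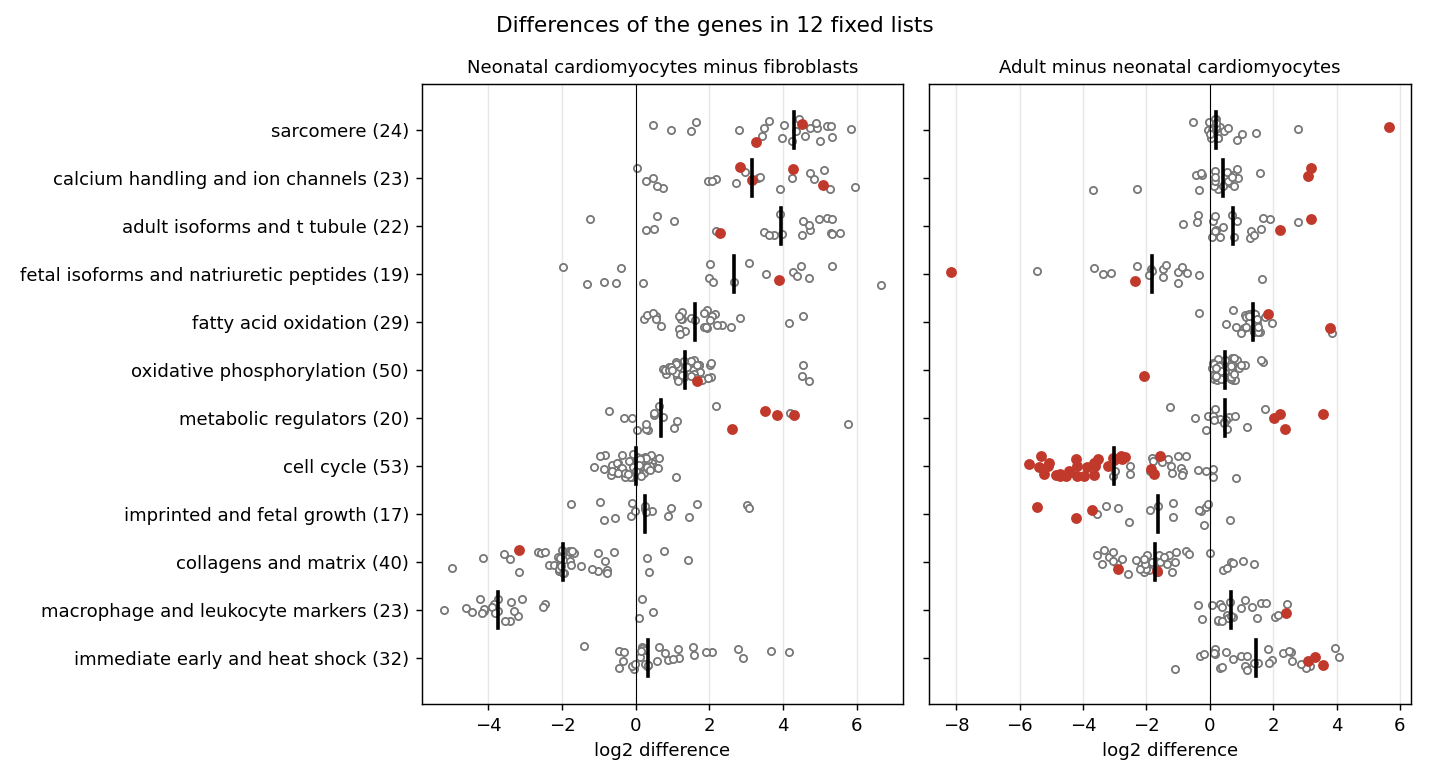
Log2 difference (horizontal axes) of each gene of fixed lists (vertical axis, with the number measured) for neonatal cardiomyocytes minus fibroblasts (left) and adult minus neonatal cardiomyocytes (right). Filled points passed an adjusted p of 0.05 over all genes, open points did not, and bars mark list medians; the cell cycle median is 0.01 on the left and −3.04 on the right.

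Adult cardiomyocytes differed from neonatal ones in 418 genes, 196 higher and 222 lower. Rpl3l, a ribosomal protein gene of striated muscle, measured 11.69 ± 0.19 in adult and 5.53 ± 0.06 in neonatal cells, 71.6-fold higher (adjusted p = 0.00696). The Z-disc gene Myot was 49.9-fold higher, and the noncoding transcript Plet1os 39.8-fold. Asb15 and Asb14, which encode SOCS box proteins, were 35.7- and 32.5-fold higher. Smco1, the carboxylesterase gene Ces1d and Timp4, an inhibitor of matrix metalloproteinases, were 33.6-, 31.4- and 29.0-fold higher. The slow skeletal troponin I gene Tnni1, used by the fetal heart, fell from 13.50 ± 0.50 to 5.33 ± 0.12 (288-fold, adjusted p = 0.0278). Below it lay Birc5, a gene of chromosome segregation, at 51.8-fold lower, Bex4 at 51.6-fold, the imprinted gene Mest at 44.3-fold, Clca3a1 at 43.2-fold, the cytokinesis gene Anln at 42.5-fold and the fibrillin gene Fbn2 at 41.6-fold. Xist, the transcript of the inactive X chromosome, was 42.6-fold lower and the Y-linked Eif2s3y 2.25-fold higher; the adult cells came from males and the neonatal ones from both sexes, per the labels.

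Cell cycle genes had the most calls of the 28 lists: 31 of 53 fell, 42 adjusted over the list alone, with a median of −3.04. Besides Birc5 and Anln, the ribonucleotide reductase gene Rrm2 fell by 5.32 and the checkpoint kinase gene Bub1 by 5.23. The camera adjusted p was 4.44e-29, and adjusted p = 0.604 with an estimated correlation. On the same arrays the median of endothelial markers was 8.63 and 7.91 in neonatal and 8.35 and 9.52 in adult cardiomyocytes, and that of fibroblast markers 7.20 and 8.15 against 6.49 and 8.05. The 31 calls became 0 without neonatal cardiomyocyte replicate 2, without either adult array, or without both neonatal replicate 2 arrays, 8 without neonatal cardiomyocyte replicate 1, and 16 without either fibroblast array; limma passed 43, 40, 41 and 44 members at unadjusted p under 0.05 where 0 were called.

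Fetal genes were lower as well. Tnni1 and the nonmuscle myosin gene Myh10 (−2.35) fell among 19 fetal isoform genes, 9 adjusted over the list alone (median −1.82). The list's median was 11.28 and 11.05 on the neonatal arrays, and 8.54 and 9.43 on the adult ones. Its members Myl7, Myl4 and Nppa were higher on adult replicate 2, by 4.97, 4.87 and 2.74. Over the whole list the adult arrays differed by −0.05 in the median (replicate 1 minus replicate 2). Mest, the transcription factor gene Plagl1 (−4.23) and Peg3 (−3.74) fell among 17 imprinted and fetal growth genes, 6 adjusted over the list alone (median −1.63); 3 of 5 Peg3 probe sets had that sign. Igf2, a fetal growth factor, differed by −3.58 ± 1.40 (SE) with an adjusted p of 0.217. Collagens and matrix had a median of −1.74; Mmp14 (−2.89) and Col4a1 (−1.67, with an adjusted p of 0.0514 in the replicate block) fell, 10 adjusted over the list alone, and Vcan differed by −3.55 (adjusted p = 0.114; 6 of 8 probe sets had that sign). The 22 TGF beta and myofibroblast genes had a median of −1.06, with 0 calls in limma, 8 at unadjusted p under 0.05 and 4 adjusted over the list alone. Epicardial markers (14 genes, median −2.07) included Tbx18, which fell by 3.29, and 6 adjusted over the list alone. These lists had camera adjusted p between 2.44e-08 and 3.18e-05, and for each adjusted p = 0.604 with an estimated correlation. The matrix median was 7.07 and 8.46 on the adult arrays, and 9.32 and 9.78 on the neonatal ones; that of 24 fibroblast markers, which had no camera call (median difference −0.34, adjusted p = 0.130), was 6.49 and 8.05 against 7.20 and 8.15.

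Fuel metabolism ran towards the adult cells. Bdh1, an enzyme of ketone use, rose by 3.79 and Decr1, of unsaturated fatty acid oxidation, by 1.83 (adjusted p = 0.0534 in the replicate block), among 29 fatty acid oxidation genes, of which 18 rose adjusted over the list alone (median 1.35). The list's median was 11.80 on neonatal replicate 1 and 10.31 on replicate 2, the array of the pair with the higher fibroblast marker median, and 12.54 and 12.46 on the adult arrays. The nuclear receptor genes Rxrg (3.58) and Ppara (2.04, with an adjusted p of 0.0510 in the replicate block), with Mlxipl (2.37) and Perm1 (2.21), rose among 20 metabolic regulators, with 4 that rose and 1 that fell adjusted over the list alone (median 0.48). All 23 TCA cycle genes (median 0.73) and 49 of 50 oxidative phosphorylation genes (median 0.47) had higher means in adult cells, but 0 of the first list was called in limma on either adjustment (10 at unadjusted p under 0.05), and in the second Cox7c fell by 2.09, with 1 that rose and 1 that fell adjusted over the list alone. The insulin-responsive glucose transporter gene Slc2a4 rose by 2.35 and Pfkfb2 by 2.19 in the glycolysis list, whose median was 0.10 while camera pointed down (adjusted p = 0.991). The adult isoform list had a median of 0.74, in which Kcnd2 (3.21) and Sgca (2.20) rose, and 3 adjusted over the list alone. Camera adjusted p was 9.44e-09 for fatty acid oxidation, 2.47e-05 for the TCA cycle, 3.21e-05 for oxidative phosphorylation, 0.0103 for regulators and 0.0390 for adult isoforms. With an estimated correlation adjusted p = 0.604, 0.634, 0.753, 0.604 and 0.762 in that order. The call for adult isoforms ended without neonatal cardiomyocyte replicate 2, adult replicate 1 or adult replicate 2 (adjusted p of 0.133, 0.102 and 0.0510), and that for regulators without neonatal cardiomyocyte replicate 2 (0.0531).

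Immediate early and heat shock genes were higher in adult cells, which were isolated by another method. Zfp36 (3.56), Atf3 (3.31) and Junb (3.09) rose, 15 of 32 rose and 1 fell adjusted over the list alone, with a median of 1.45, and Fosb differed by 4.09 (adjusted p = 0.0998). Inflammation genes had a median of 1.47 with 0 called in limma, 13 at unadjusted p under 0.05 and 1 adjusted over the list alone; Cxcl2 differed by 4.55 (adjusted p = 0.112). Their median was 6.52 and 6.39 on the neonatal arrays but 7.13 and 8.86 on the adult ones, and that of leukocyte markers 6.79 and 5.39 against 6.49 and 7.77. Camera adjusted p was 8.59e-07 and 0.000223, and adjusted p = 0.604 with an estimated correlation for each. The other 15 lists had no camera call, with adjusted p between 0.0556 and 0.991. Hrc rose by 3.10 and Kcnd2 by 3.21 among calcium and channel genes (median 0.41), and Tbx20 fell by 1.88 among transcription factors (median −0.33). Vtn rose by 3.55 among smooth muscle and pericyte markers, Cd163 by 2.39 among leukocyte markers and Fgf16 by 1.92 among paracrine factors, while Ncam1 fell by 2.89 among Schwann and neural markers (6 of 7 probe sets had that sign; the list's median was 0.05 and camera pointed down). Sarcomere genes had a median of 0.20, with Myot the only call. Myh6 and Tnnt2 differed by 0.09 and −0.03 near the top of the range, where RMA values can compress differences.

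The count of 418 became 163 without neonatal cardiomyocyte replicate 1, 164 without either fibroblast array, and 0 without neonatal cardiomyocyte replicate 2 or either adult array, while 2729, 2572 and 3303 genes passed limma at unadjusted p under 0.05. In those 3 fits 0 members of any list were called. Without neonatal cardiomyocyte replicate 1, the calls went from 2 to 4 for fatty acid oxidation, from 3 to 5 for immediate early and heat shock genes, and to 1 for regulators and for imprinted genes. Without either fibroblast array, 1 immediate early gene rose and 0 fatty acid oxidation, adult isoform and matrix genes were called (20, 9 and 15 at unadjusted p under 0.05). Leaving out either fibroblast array gives the same fit here, since fibroblasts do not enter this difference and a lone fibroblast array adds no residual. In these fits with an array left out, counts of other lists also moved, among them fetal isoform, calcium and channel, glycolysis and paracrine genes. The count was 114 with the groups that the titles give. Of all genes 57.7% had non-overlapping arrays, against 33.3% by chance, with 6172 higher and 4329 lower in adult cells. The 33.3% takes all arrays to have the same distribution, but the adult arrays had narrower quartiles than the others.

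**Figure D3:**
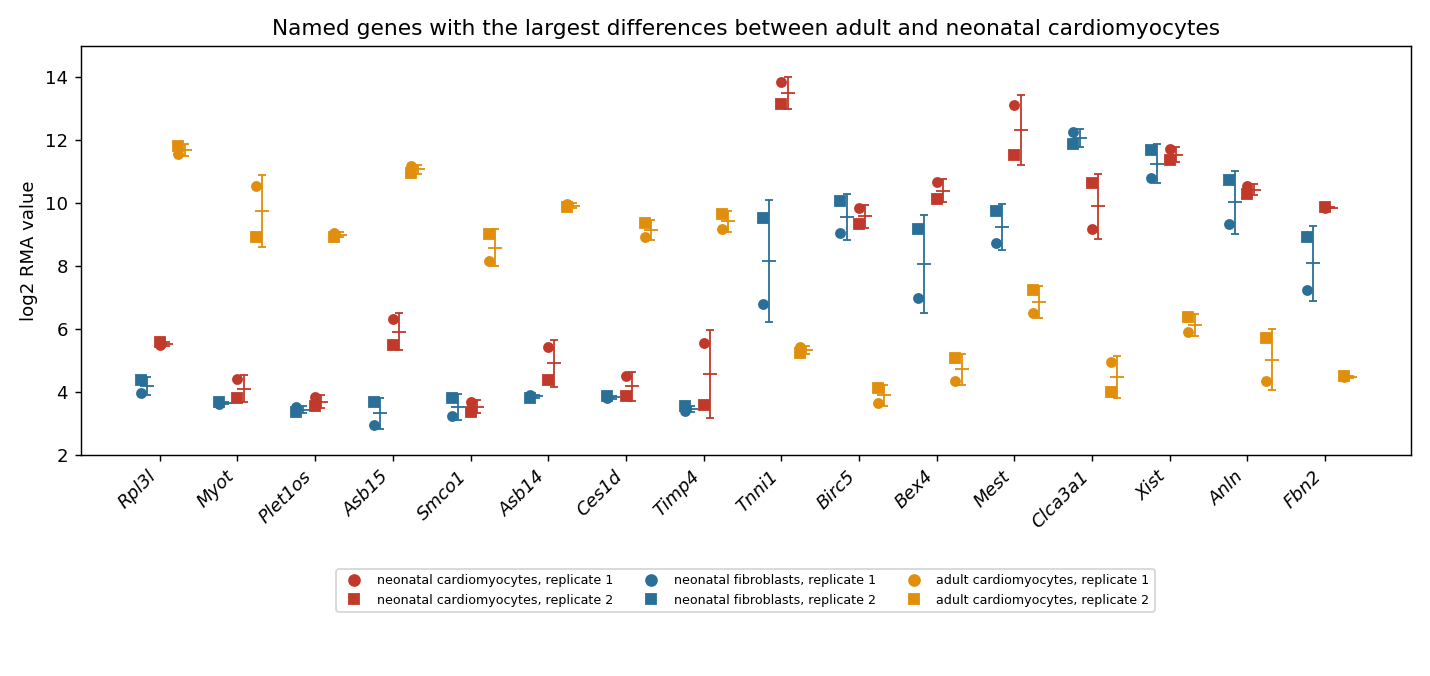
Log2 RMA value (vertical axis) of the named genes with the largest differences between adult and neonatal cardiomyocytes, on all 6 arrays; small symbols are arrays, and horizontal marks with bars are group means ± SD (n = 2). Tnni1 lies at 13.50 ± 0.50 in neonatal and 5.33 ± 0.12 in adult cardiomyocytes.

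Adult cardiomyocytes against neonatal fibroblasts combine cell type with age, and differed in 3829 genes, 1829 higher and 2000 lower. Asb15 and Rpl3l were 217- and 183-fold higher, followed by the mitochondrial creatine kinase gene Ckmt2 (177-fold), Txlnb (149-fold) and Rgcc (124-fold). Cemip, a hyaluronan-degrading factor, was 340-fold lower at 3.78 ± 0.33 against 12.19 ± 0.12 (adjusted p = 0.0428), followed by Clca3a1 (194-fold), Scel (114-fold, with 1 of 2 probe sets of that sign), Cthrc1 (103-fold) and the crosslinking enzyme gene Lox (99.5-fold). In cardiomyocytes 19 of 24 sarcomere genes rose (Tcap by 6.39) and 15 of 23 calcium and channel genes (Hrc by 6.26), with 24 and 18 adjusted over the list alone. Of the energy lists, 49 of 50 oxidative phosphorylation genes rose (Cox7a1 by 6.38), 25 of 29 fatty acid oxidation genes (Pdk4 by 6.03), 21 of 23 TCA cycle genes and 11 of 20 regulators, while 1 regulator fell (Perm1 rose by 5.72, Ppara by 4.66), with 49, 28, 22 and 14 that rose adjusted over the list alone, where 1 oxidative phosphorylation gene and 1 regulator fell. Of 40 matrix genes 27 fell (Col11a1 by 6.48, Col1a1 by 5.45), and 10 of 24 fibroblast markers (Tcf21 by 5.33; 1 other marker rose), 8 of 14 epicardial markers (Sema3d by 5.76), 11 of 22 TGF beta genes and 42 of 53 cell cycle genes (Birc5 by 5.67), with 31, 15, 10, 17 and 45 that fell adjusted over the list alone, where 1 fibroblast marker and 1 TGF beta gene rose. Immediate early and heat shock genes had 20 that rose and 1 that fell (23 and 1 adjusted over the list alone), among them Fosb (6.88) and Atf3 (5.37). Of 22 adult isoform genes 14 rose (Ckmt2 and Tcap among them), with 18 adjusted over the list alone, and of 21 glycolysis genes 9 rose and 1 fell on both adjustments. Cardiac transcription factor genes had 8 that rose and 1 that fell, on both adjustments, and 6 of 17 imprinted genes fell, with 8 adjusted over the list alone. All of these lists passed camera, and with an estimated correlation adjusted p = 0.408 for fibroblast markers, 0.429 for transcription factors, 0.488 for imprinted genes and 0.349 for each of the others. Fetal isoforms had 4 that rose and 4 that fell, and inflammation genes 3 and 3; their medians were 0.72 and 0.10 while camera pointed down (adjusted p = 0.877 and 0.950).

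Smaller lists divided. Among leukocyte markers Cd68 (−4.00), Ctss (−3.93) and Lyz1 (−2.74) fell and Cd163 rose (2.47), with 1 that rose and 5 that fell adjusted over the list alone, and 6 of 19 endothelial markers rose, with 7 adjusted over the list alone. Camera adjusted p was 0.00158 and 0.0104, and adjusted p = 0.605 and 0.488 with an estimated correlation; without adult replicate 2 the endothelial call ended (adjusted p of 0.0755). Asns (−5.21) and Adm (−4.26) fell while Bnip3 (2.95), Egln3 (1.90) and Herpud1 (1.85) rose among 21 hypoxia and amino acid stress genes. Btg2 rose by 2.80 and Rbl1 fell by 2.95 among cell cycle inhibitors, with 2 of 4 Rbl1 probe sets of that sign, and Tubb3 (−4.59) and Ncam1 (−3.45) fell among Schwann and neural markers. Xist fell by 5.12, and Uty (1.23) and Eif2s3y (1.18) rose. The count of 3829 became 1083 without fibroblast replicate 1, 1941 without fibroblast replicate 2, 350 without adult replicate 2 and 0 without adult replicate 1 (4591 at unadjusted p under 0.05 in limma); the titles' grouping gave 137. Without adult replicate 1, 0 members of any list were called. Without adult replicate 2, 2 sarcomere, 4 calcium and channel, 2 adult isoform, 1 oxidative phosphorylation, 2 glycolysis, 4 regulator and 2 immediate early and heat shock genes rose. There 9 matrix, 9 cell cycle, 4 fibroblast, 4 imprinted and 2 epicardial genes fell, and 0 fatty acid oxidation, TCA cycle, transcription factor, TGF beta and endothelial genes were called (27, 22, 9, 18 and 6 at unadjusted p under 0.05). Without fibroblast replicate 1, 20 oxidative phosphorylation, 16 fatty acid oxidation, 12 TCA cycle, 6 immediate early and heat shock and 3 transcription factor genes rose, 8 matrix, 4 epicardial, 2 fibroblast, 2 TGF beta and 2 imprinted genes fell, and 0 endothelial markers were called (7 unadjusted). Without fibroblast replicate 2, 10 immediate early and heat shock and 5 transcription factor genes rose, and 8 matrix, 8 leukocyte, 3 fibroblast, 3 TGF beta and 3 imprinted genes fell. Without either neonatal cardiomyocyte array 10 endothelial markers rose. Of all genes 68.0% had non-overlapping arrays, against 33.3% by chance, with 6873 higher and 5493 lower in adult cells. The narrower quartiles of the adult arrays limit this comparison too.

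Both cardiomyocyte groups exceeded fibroblasts in 114 genes, and 23 genes were lower in both. Independent lists of these lengths would share 12.4 and 2.86 genes, which leaves out the shared arrays. In 100 simulations of unchanged groups against shared fibroblast arrays the means were 0 and 0.01; with no real effects few genes are called, so these do not measure what sharing adds to the 114. The log2 differences of the comparisons correlated at 0.768 across genes (0.498 simulated), with a covariance of 0.866 (0.102 simulated). With the fibroblast arrays divided, 1 to each comparison, the correlation was 0.541 and the covariance 0.721 with replicate 1 as the control of the neonatal cells, and 0.707 and 0.793 with replicate 2. The first division gave 184 genes higher in both (8.63 for independent lists) and 27 lower in both (4.32). The second gave 0 and 0, as limma called 0 genes between the neonatal cell types there, with 903 genes higher in both at unadjusted p under 0.05. Each division leaves 1 control array per comparison, so part of the excess in the undivided counts may still come from sharing them. Both fits of a division also estimate each gene's variance from the same cardiomyocyte arrays. Their calls are therefore not independent, and the values for independent lists are no reference for the divided counts. The 114 became 243 without neonatal cardiomyocyte replicate 2, 235 without fibroblast replicate 2, and 0 without any other array or with the replicate block.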

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

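Removal of both neonatal replicate 2 arrays, the division of the fibroblast arrays between the comparisons, and the re-counts of list members were chosen after the data were seen. Quantile normalization, median centring and a 2-fold minimum kept each of the 4 counts within 1.5 times. Of the settings run, only the titles' grouping turned the direction of a named gene. The genes called moved more than the counts. Of the 149 genes, 116 were still called with quantile normalization and 55 with the mean of a gene's probe sets. Of the 418 genes, 373 and 287 were still called in that order. Among named genes called, the mean kept 16 of 34 between the neonatal cell types and 31 of 45 between the cardiomyocyte groups. With the replicate block the neonatal comparison called 0 genes (3678 at unadjusted p under 0.05 in limma) and the genes higher in both cardiomyocyte groups 0, and the calls of Ppara, Decr1 and Col4a1 between the cardiomyocyte groups ended. It changed no other call of a named gene or list, and the other counts stayed within 1.5 times.

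For neonatal cardiomyocytes against fibroblasts, 149 genes became 248 with an intensity trend, 342 without the dimmest genes (fewer tests), 59 with the mean of a gene's probe sets, and 0 with every probe set by itself (4949 unadjusted), with only the 4 arrays compared (2532), with the titles' grouping (232), without both arrays of disagreeing labels (1461) and without both neonatal replicate 2 arrays (3509). With an array left out it ranged from 0 to 437. For adult against neonatal cardiomyocytes, 418 became 164 with only the 4 arrays, 114 with the titles' grouping, and 0 without both arrays of disagreeing labels (3845) or both neonatal replicate 2 arrays (2559), and 0 to 164 with an array left out. For adult cardiomyocytes against fibroblasts, 3829 became 137 with the titles' grouping, 717 without both arrays of disagreeing labels and 1574 without both neonatal replicate 2 arrays, and 0 to 3823 with an array left out. The 114 genes higher in both became 183 with a trend, 267 without the dimmest genes, 38 with the mean, 0 with every probe set, only 4 arrays, the titles' grouping, or either pair of arrays removed, 184 and 0 with the fibroblast arrays divided between the comparisons, and 0 to 243 with an array left out. Cell cycle calls, 31, became 16 with only the 4 arrays, 0 without both arrays of disagreeing labels (45 unadjusted) or both neonatal replicate 2 arrays (44), and 0 to 16 with an array left out. A group left with 1 array is assumed to vary like the others. For a comparison of the other groups, that fit is the same as with only the 4 arrays compared. Fewer arrays leave fewer residual degrees of freedom; beyond that the cause was not tested. Of the 149 and 418 genes, 149 and 418 kept their direction with any array left out. This outcome was nearly fixed in advance, since the genes were chosen on the same arrays for large differences. An array of the group not compared leaves the difference unchanged. List calls numbered 18, 13 and 18 in the 3 comparisons, 18 to 21, 12 to 19 and 17 to 19 with an array left out, and 0, 0 and 0 with an estimated correlation (3, 1 and 0 at unadjusted p under 0.05 in camera).

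With the titles' grouping, differences between neonatal cardiomyocytes and fibroblasts reversed, with a log2 difference of Txlnb −0.73, Klhl41 −0.80, Kcnj3 −0.68, Rnf207 −1.01, Strip2 −0.995, Tox3 −0.82, Casq1 −0.39, Smyd1 −0.79, Des −0.29, Xirp1 −0.91, Cacnb2 −0.38, Kcnq1 −0.53, Hrc −0.66, Tnnt1 −0.72, Sgca −0.22, Mdh1 −0.41, Ndufs7 −0.20, Ldhb −0.30, Ppara −0.53, Ppargc1b −0.82, Esrrg −0.9995, Perm1 −0.35, Fgf1 −0.21, Csrp3 −1.87, Pdk4 −1.39, Cox7a1 −1.62, Myh6 −1.48 and Tnni3 −2.33, and of Scel 0.77, Ccn5 0.60, Ms4a7 0.38, Tcf21 0.34, Kcnj15 0.30, Lgi2 0.32, Clec4d 0.35, Loxl1 0.47, Itgb5 0.28, Col8a1 3.14, C1qa 0.33 and Cd68 0.90. The list medians became −1.38 for sarcomere, −0.66 for calcium handling and ion channels, −0.24 for cardiac transcription factors, −0.78 for fetal isoforms and natriuretic peptides, −1.49 for adult isoforms and t tubule, 0.42 for collagens and matrix, 0.44 for TGF beta and myofibroblast, −0.71 for fatty acid oxidation, −0.44 for TCA cycle, −0.39 for oxidative phosphorylation, −0.26 for glycolysis, −0.29 for metabolic regulators, −0.87 for endothelial markers, 0.76 for macrophage and leukocyte markers, 0.79 for epicardial and mesothelial markers, −0.35 for immediate early and heat shock and 0.058 for inflammation and interferon. In the comparisons with adult cardiomyocytes, that grouping turned the camera direction of cardiac transcription factors between adult cardiomyocytes and fibroblasts (median 0.16) and gave Tnnt2 a difference of 1.19 between adult and neonatal cardiomyocytes. It also ended list calls, with adjusted p of 0.636 for fibroblast markers between the neonatal cell types, where the median was 0.17, of 0.0554 for fetal isoforms and 0.0900 for inflammation between the cardiomyocyte groups, and of 0.583 for glycolysis, 0.287 for endothelial and 0.795 for leukocyte markers between adult cardiomyocytes and fibroblasts. The cause is the exchange of the 2 arrays itself. RMA values near the floor or the top of the range can compress differences.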

Other observations

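The tests of endothelial markers, of cell cycle against fibroblast genes, of the titles, of the atrial list, and of matrix genes over complete lists were chosen after the result was seen, as were the 4 definitions of abundant genes and the 6 choices of genes for RNA shares.

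Adult cardiomyocyte replicates differed in several genes typical of atrial muscle, among others. The atrial light chains Myl7 and Myl4 measured 8.01 and 8.02 on adult replicate 1 and 12.98 and 12.89 on replicate 2, and Sln, an atrial regulator of the calcium pump, 6.04 and 11.99; the natriuretic peptide gene Nppa measured 11.11 and 13.84. The ventricular gene Irx4 measured 7.91 and 7.75. A list of 10 further atrial markers was then written down, of which 8 were measured. Of these, 7 were higher on replicate 2, but their median difference of 0.46 log2 units exceeded that of only 96.4% of 10000 random lists matched on mean level, so chance is not excluded two-sided at 0.05. Pam, Dkk3 and Nr2f2 were higher by 2.93, 2.25 and 2.01, Stard10 by 0.78, while Bmp10, Kcna5 and Gja5 differed by 0.14, 0.09 and 0.00 and Kcnk3 by −0.60. Several of these genes, such as Nr2f2, Dkk3 and Pam, are not confined to atrial muscle. Markers of other cells were also higher on adult replicate 2, with medians of 8.46 against 7.07 for matrix genes, 8.05 against 6.49 for fibroblast, 9.52 against 8.35 for endothelial and 7.77 against 6.49 for leukocyte markers. These are values of single arrays, and the explanation stays open.

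Cell cycle genes were lower in adult than in neonatal cardiomyocytes, by −3.04 log2 units in the median. Fewer endothelial cells among the adult cells are argued against. The endothelial median fell by at most 0.28 between any neonatal and any adult array, where the cell cycle median fell by at least 2.82. The markers follow the amount of endothelial RNA and not which cells carried the cell cycle transcripts, so an endothelial source of these stays open. Fibroblasts carried over into the neonatal cardiomyocytes are argued against on replicate 1 and less clearly on replicate 2. Relative to fibroblasts, the cell cycle median lay above that of abundant fibroblast and matrix genes by 2.63 to 2.82 on replicate 1. On replicate 2 it lay above by 0.997 to 1.14 (permutation p = 1e-05 for each, the smallest possible). The permutation shuffled genes within 1 array, so its p does not measure variation between preparations. The lowest difference, 0.997, missed the bound of 1 set for exclusion. Those fibroblast and matrix genes lay at 17.3% to 19.8% of their fibroblast level on replicate 1 and 35.2% to 39.0% on replicate 2. Only they had a level cutoff, while all 53 cell cycle genes entered, so a contribution of fibroblasts stays open. Age, sex and isolation method differ together between the groups and also stay open, untested.

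Matrix genes were lower in adult than in neonatal cardiomyocytes, as they would be if fewer fibroblasts were carried over into the adult preparations, which the fibroblast markers should then follow. Among genes called lower in adult cardiomyocytes than in fibroblasts, the median of 27 matrix genes lay −0.43 log2 units from that of 10 fibroblast markers (−1.57), with a two-sided permutation p of 0.211. That choice of genes uses the adult arrays and so favours markers that fell. Over the complete lists, 40 matrix genes had a median of −1.74 and 24 fibroblast markers −0.34, a difference of −1.40 (two-sided permutation p = 0.00352). Both permutations shuffled genes between the lists as if independent, so their p does not measure variation between preparations. The outcome depends on the genes chosen, so carried-over fibroblasts stay open, as do age, sex and isolation method, untested.

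Cardiomyocyte genes were higher on fibroblast replicate 2 than on replicate 1; Myl2, among the most abundant, measured 12.50 and 8.41. A wrong grouping of the replicate 1 arrays is argued against, since the sarcomere median of the array grouped as cardiomyocyte replicate 1 exceeded that of fibroblast replicate 1 by 5.93 log2 units. Carried-over cardiomyocytes would need a like share of cardiomyocyte RNA in each set of genes. Shares were taken for genes with a mean neonatal cardiomyocyte level from 10 to below a limit of 13 to 14. They also had to exceed fibroblast replicate 1 by at least 3 or 4 log2 units. The choices left out the most abundant genes, Myl2 among them, and kept 9 to 15 of the 24 sarcomere genes. Myl2 measured 14.50 and 14.38 on the neonatal cardiomyocyte arrays and would need a larger share than the medians below. The comparison therefore covers only the genes kept. Quartiles of the share ran from 4.14% to 13.9% over the sets and choices, so only medians are compared. The median share lay between 6.78% and 8.34% for sarcomere genes, calcium and channel genes and other cardiomyocyte genes, and the highest was at most 1.23 times the lowest over the 6 choices. This is consistent with carried-over cardiomyocytes or their RNA, although the labels describe a separation and a dye check for remaining cardiomyocytes, and no biological explanation was tested.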
